A study of Mus musculus with 2 samples.

How the data were processed

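H3K27me3 ChIP-seq of limb tissue from embryos of embryonic day 10.5 was analysed in 2 biological replicates, pools of 69 and 51 embryos of both sexes. Replicate numbers and pool sizes were taken from the sample labels, which describe separate tissue pools. Peak lists were the only measurements used; alignments and signal tracks were not analysed here, and the read depth per sample is unknown.

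The authors deposited 4 peak lists in narrowPeak format on build mm10, per the labels' file descriptions. Per those descriptions, each replicate's list was made from its own filtered alignments and a control, the pooled list from both replicates' alignments and both controls, and the replicated list from the replicates' lists and the pooled list. The fold enrichment of each peak is a ratio as the authors' peak caller gave it, and the p-value and q-value of each peak were deposited as −log10 values, per the column order of the format named in the labels. The smallest −log10 p in any list was above 2. The peak caller, the aligner, their settings and the rule behind the replicated list are not given in the sources used here. Narrow peaks can split a broad domain of this mark into many peaks, so both peak number and covered length are given, and a longer list can reflect deeper sequencing as well as more marked sequence.

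Peaks on chromosomes 1 to 19 and X were used. Gene positions came from GENCODE mouse release 21 of the M series and sequence from the GRCm38 reference, the assembly that mm10 names; all peak ends lay within its chromosomes. A gene was called marked when a replicated peak overlapped any of its protein-coding TSSs within 1 kb. The covered share of a gene's promoter is that of its best covered TSS window unless stated. CpG observed/expected ratios and GC content were computed over the same window at the most 5' TSS. Peaks were counted as shared at an overlap of at least 50% of the shorter peak. Covered bases were assigned to promoter, exon, intron or intergenic sequence in that order. Domains were made by joining replicated peaks across gaps of up to 3 kb and ranked by covered length. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.

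Measures were described per replicate with their mean and SD (n = 2), since 1 group with 2 replicates allows no test between groups. Shares of peaks come from complete lists; counting intervals (Wilson, 95%) of the shares found in the other replicate were 64.7% to 65.2% for replicate 1 and 41.1% to 41.7% for replicate 2, and cover counting error only. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes on these chromosomes, and p-values were adjusted by the Benjamini-Hochberg method over 24 lists, 18 written by hand and 6 taken by symbol pattern. All members of the hand-written lists were found in the annotation. As an alternative, each list was compared with 10000 random lists matched in 20 bins of promoter CpG ratio.

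The lists, tests, alternatives and the rule for named genes of the report were fixed before the data were examined, except where stated. By that rule the text names up to 4 marked members of each list with the longest covered length within 5 kb of the TSS and up to 4 unmarked members, genes in the 10 widest domains, genes at the 10 strongest peaks, all Hox genes, and up to 10 genes with promoters covered in 1 replicate only. Genes next to a named region are named by position. Alternatives covered the promoter window (500 bp and 2.5 kb), the TSS used, the peak list, a stricter −log10 q of at least 2, the overlap required, the joining gap (1 and 5 kb), 1 gene per 100 kb, and each replicate's own list in place of the replicated one. Restriction to autosomes, the 1 Mb bins by gene number and the match of each X bin to the 20 autosomal bins of its gene number class nearest in GC content were added after the X chromosome was seen to stand apart.

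The overlap, joining and list tests were tested on simulated data. Of 133099 simulated peaks none was wrongly called shared or unshared. The design left no room for error, as shared peaks were slightly shifted copies and the others overlapped no peak. This checks the counting only and says nothing about partly overlapping peaks. For the list comparison over 21670 genes, 200 genes in 10 lists of 20 were given 5-fold raised odds of marking, and Fisher's exact test called 9 of these lists at an unadjusted exact p under 0.05. It called all 10 at 10-fold odds. Among 500 unchanged lists it called 3% and 4.2% in these runs. Marks were drawn independently for each gene and lists were drawn at random. These rates therefore do not cover lists of neighbouring genes that share a domain.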

Results

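H3K27me3, the histone H3 mark that Polycomb complexes place on silent genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of B6NCrl mouse embryos at embryonic day 10.5, when each limb is a bud of mesenchyme under a thin ectoderm. The data comprised 1 group of 2 biological replicates. Replicate 1 came from a pool of 69 embryos and replicate 2 from a pool of 51, and both pools held male and female embryos. There was no second condition, so the values below describe the mark in this tissue and the spread between its replicates, and no group was tested against another. The read depth behind each list is unknown, because the peak files give no read counts.

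In the list of replicated peaks, which the authors derived from both replicates' lists and the pooled list, the mark covered 86.3 Mb in 71422 peaks, or 3.28% of the 19 autosomes and the X chromosome on build mm10. The median peak was 607 bp wide and the widest 89965 bp. Replicate 1 on its own gave 123895 peaks over 61.5 Mb and replicate 2 gave 133099 peaks over 90.5 Mb, a mean of 76.0 ± 20.5 Mb (SD, n = 2). Peak numbers differed less between the replicates, with a mean of 128497 ± 6508 (SD, n = 2), than covered length did, and the median width was 256 bp in replicate 1 and 320 bp in replicate 2.

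The mark lay preferentially at promoters. Of 21670 protein-coding genes, 5915 (27.3%) had a replicated peak within 1 kb of an annotated transcription start site (TSS), and 4018 (18.5%) had at least 50% of that window covered. The replicates' own lists marked 28.3% and 29.8% of the genes (29.0 ± 1.05%, SD, n = 2). Promoter windows held 11.5% of the covered bases and 2.5% of the genome, a 4.58-fold excess (4.83 ± 0.767 over the replicates' own lists, SD, n = 2). Exons outside promoters showed a 1.77-fold excess, introns a ratio of 1.01, and intergenic sequence a ratio of 0.758. At the most 5' TSS, where 5460 genes were marked and 16210 were not, marked promoters were richer in CpG than unmarked promoters, with a median CpG observed/expected ratio of 0.532 against 0.438 and a median GC content of 55.2% against 49.7%. The 2 classes overlapped broadly, since 37.1% of marked and 33.7% of unmarked promoters had a ratio of 0.6 or more. Of 1463 olfactory and vomeronasal receptors, whose promoters are CpG-poor, 1459 were unmarked at every TSS. The classes were not compared without this family, so its part in the CpG difference is unknown.

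Neural, kidney and gonad regulators were marked without exception. All 35 neural transcription factors of the list fixed in advance had a marked promoter, in the replicated list and in each replicate, and so did all 12 kidney and gonad regulators. Neurog3, Pou4f2, Olig2 and Neurod2, which specify or mature neurons and glia, were covered over the whole 5 kb on either side of the TSS, at peak folds of 23.0, 19.2, 17.5 and 17.1. Pax2, Emx2, Six2 and Sim1 headed the kidney and gonad list, with folds of 15, 12.7, 10.8 and 10.2. Of 19 endoderm and gut genes 14 were marked (73.7%), led by Ptf1a, Onecut1, Cdx2 and Nkx2-1, whereas the unmarked members were the transcription factor genes Hnf4a and Isx and the liver products Afp, Ttr and Alb, the last named after its value was seen. Of 16 heart genes 11 were marked (68.8%), among them the regulators Gata4, Tbx1, Nkx2-5 and Hand1 at folds of 14.3, 14.2, 14.2 and 9.90. The 5 unmarked members were the contractile and secreted products Myh6, Myh7, Nppa, Bmp10 and Tnnt2 (the last named after its value was seen). Myl7, a contractile gene of the same list that was also named afterwards, was thus among the marked members. Each of these 4 lists was marked more often than all other protein-coding genes (27.2% to 27.3%) by Fisher's exact test, two-sided, with adjusted p of 8.18e-20 (neural), 4.07e-07 (kidney and gonad), 5.43e-05 (endoderm) and 0.000976 (heart), adjusted by the Benjamini-Hochberg method over 24 lists. Genes are not independent replicates and neighbouring genes can share a domain, so these p-values describe the lists and not a spread between animals.

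Limb regulators were marked often, but limb transcription factors less completely than neural ones. Among 31 limb bud transcription factors 25 were marked (80.6%; 77.4% in replicate 1 and 83.9% in replicate 2; odds ratio 11.1, adjusted exact p = 2.46e-09). Emx2, Lhx2, Pitx1, which acts in the hindlimb, and Tbx5, which acts in the forelimb, had their whole promoter windows covered. No replicated peak reached the promoters of Prrx1, Gli3, Pbx1 and Pbx2, and Meis1 and Meis2, named after their values were seen, were the other unmarked members. Expression was not measured, so marked and unmarked members were not compared by it. Of 30 limb signalling genes 25 were marked (83.3% in both replicates and in the replicated list; odds ratio 13.4, adjusted exact p = 7.23e-10). En1 and Wnt7a of the dorsal-ventral axis and Fgf8 and Wnt3 of the apical ridge carried folds of 15.4, 18.0, 15.9 and 14.9. The unmarked members were Fgf10, the mesenchymal signal of limb outgrowth, and Dusp6, Etv5, Spry2 and Spry4, the last named after its value was seen. The median limb transcription factor had 68.6% of its promoter window covered, against 100% for the median neural factor.

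Genes of the surface ectoderm, the skeleton and muscle were also mostly marked in this tissue. Of 17 ectoderm and apical ridge markers 15 were marked (88.2%; odds ratio 20.0, adjusted exact p = 5.65e-07), including Tfap2a, Sp9, Sp8 and Esrp1 at folds of 11.4, 9.09, 10.9 and 9.55, while Trp63 and Krt5 were not. Cartilage and bone genes (12 of 15, with Barx1, Nkx3-2, Ihh and Runx2 marked and Sox5, Col9a1 and Col10a1 unmarked) and skeletal muscle genes (12 of 15, with Pax7, Pax3, Lbx1 and Six1 marked and Six4, Actc1 and Ckm unmarked) had the same count, an odds ratio of 10.7 and an adjusted exact p of 5.43e-05 each. The call for cartilage and bone was lost when 1 gene per 100 kb was kept (adjusted exact p = 0.385). Of 13 endothelial markers 7 were marked (Sox17, Flt1, Kdr and Esam among them; Cdh5, Emcn, Fli1 and Pecam1 unmarked), which did not pass the threshold (adjusted exact p = 0.0628). Blood markers stood at 8 of 15 (adjusted exact p = 0.0474), with Tal1 and Runx1 marked over their whole promoter windows and Gata1, Gypa, Csf1r and Hbb-bh1 unmarked; that call was lost in 5 of the 11 alternatives, with adjusted exact p up to 0.120.

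**Figure D1:**
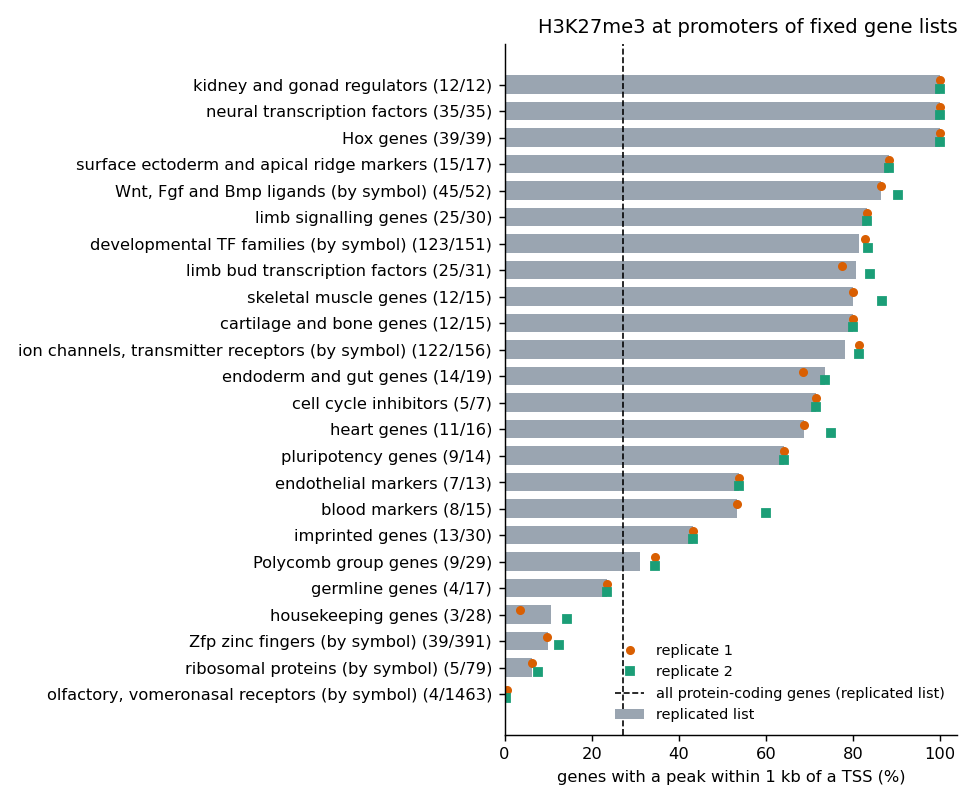
Share of genes with an H3K27me3 peak within 1 kb of a TSS (x axis, %) for the 24 gene lists, with marked and total genes in parentheses; bars give the replicated list, circles replicate 1, squares replicate 2 and the dashed line all protein-coding genes (27.3%). Hox genes, neural factors and kidney and gonad regulators lay at 100%, and ribosomal proteins (6.33%) and chemosensory receptors (0.273%) at the bottom.

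Families of developmental genes taken by symbol were marked more often than other genes, and zinc finger, ribosomal protein and chemosensory receptor genes less often. Of 151 members of the Sox, Fox, Pax, Tbx, Lhx, Irx, Gata, Nkx, Dlx, Pou, Zic and sine oculis homeobox families taken by symbol, 123 (81.5%) were marked (odds ratio 11.9, adjusted exact p = 8.12e-43), with Pou4f2, Pax7, Nkx1-1 and Six3 at the head and the broadly expressed Foxk1, Foxk2 and Foxj3 and the epithelial Foxi1 among the unmarked members. The share was 86.5% of 52 genes with Wnt, Fgf or Bmp symbols (adjusted exact p = 2.30e-18), led by Wnt10b, Wnt7b, Wnt10a and Fgf11. It was 78.2% of 156 ion channels and transmitter receptors (adjusted exact p = 3.44e-39), led by Grik3, Grin2c, Kcnj4 and Kcnq4. By contrast 39 of 391 Zfp zinc finger genes were marked (9.97%; odds ratio 0.290, adjusted exact p = 9.28e-17), 5 of 79 cytosolic ribosomal protein genes (6.33%; adjusted exact p = 6.55e-06) and 4 of 1463 olfactory and vomeronasal receptors (0.273%; adjusted exact p = 1.91e-200). The zinc finger result is not one of low CpG content, since random lists matched on promoter CpG averaged 34.7% marked; for the receptors, whose promoters are CpG-poor, the matched lists averaged 10.6%. Of the marked ribosomal genes, Rps4x, Rpl36a and Rpl10 are X-linked, and autosomal Rpl3 has its TSS 0.524 kb from that of Syngr1, a synaptic vesicle gene, inside a domain that reached a fold of 12.3.

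Housekeeping and other control lists gave mixed results. Of 28 housekeeping genes 3 were marked (10.7%; 3.57% in replicate 1 and 14.3% in replicate 2), and the difference from other genes did not pass the threshold (adjusted exact p = 0.0628). Of these, Pgk1 and Hprt lie on the X chromosome and Actb on chromosome 5; on the autosomes alone, an alternative chosen after the X was seen to stand apart, 1 of 26 was marked and the list was lower than other genes (adjusted exact p = 0.00833). Cell cycle inhibitors were marked in 5 of 7 cases (adjusted exact p = 0.0254), among them Cdkn2a, Cdkn2b, Cdkn2c and Cdkn1a but neither Cdkn1b nor Cdkn2d. Of 14 pluripotency genes 9 were marked (64.3%; adjusted exact p = 0.00586), with Sox2, Prdm14, Esrrb and Utf1 marked and Dppa2, Dppa4, Dppa5a and Lin28a unmarked. Neither the 29 Polycomb group genes (9 marked, including Phf19, Cbx4, Cbx8 and Bmi1; adjusted exact p = 0.707) nor the 17 germline genes (4 marked: Tdrd1, Taf7l, Piwil1 and Ddx4; adjusted exact p = 1) differed detectably from other genes. Of 30 imprinted genes 13 were marked (43.3%; adjusted exact p = 0.0687), with the whole promoter windows of Igf2, Grb10, Zdbf2 and Ascl2 covered.

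All 39 Hox genes, the homeobox genes that pattern the body axis and the limb, had a marked promoter in both replicates. The adjusted exact p was 5.57e-22, and 0.00698 with 1 gene per 100 kb kept, since clustered genes share domains. But the 4 clusters differed in how far they were covered. HoxC (chromosome 15, 102921103 to 103036852) was covered over 99.3% of its length (95.7 ± 3.21% over the replicates' own lists, SD, n = 2) and HoxB (chromosome 11, 96194316 to 96368256) over 81.1% (74.2 ± 11.1%). The HoxB length includes the stretch between the end of Hoxb13 (96197447) and the start of Hoxb9 (96271457), which holds no other Hox gene. The domain over Hoxb9 to Hoxb1 (96246620 to 96385415), bounded by its own peaks, was 93.1% covered in the replicated list. HoxD (chromosome 2, 74668310 to 74765142) reached 71.2% (60.7 ± 9.12%) and HoxA (chromosome 6, 52155590 to 52260880) 62.2% (50 ± 3.75%). The order HoxC, HoxB, HoxD, HoxA was the same in each replicate, and HoxC and HoxA differed by far more than the spread between replicates. Within HoxD, the promoter windows of Hoxd13 and Hoxd12 were covered completely and that of Hoxd11 over 98.8%. Coverage then fell to 83.0% at Hoxd10, 27.5% at Hoxd9 and 47.1% at Hoxd8, and it stood at 100% again at Hoxd1. In replicates 1 and 2 the values were 54.5% and 66.8% at Hoxd10, 45.1% and 31.5% at Hoxd9, and 54.2% and 30.8% at Hoxd8. Hoxd3 and Hoxd4 depended on the TSS taken: 100% and 93.6% at the best covered TSS, which is the value given for each gene unless stated, and 26.5% and 60.8% at the most 5' TSS. In HoxA the values ran from 29.3% at Hoxa5 to 89.5% at Hoxa13, but which promoter was lowest changed with the TSS and the list: Hoxa9 (5.50%) at the most 5' TSS, Hoxa4 (8.45%) in replicate 1 and Hoxa9 (12.8%) in replicate 2. Single promoters differed between replicates in both directions: Hoxb2 was covered over 27.4% in replicate 1 and 88.0% in replicate 2, and Hoxa9 over 67.3% and 12.8%.

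**Figure D2:**
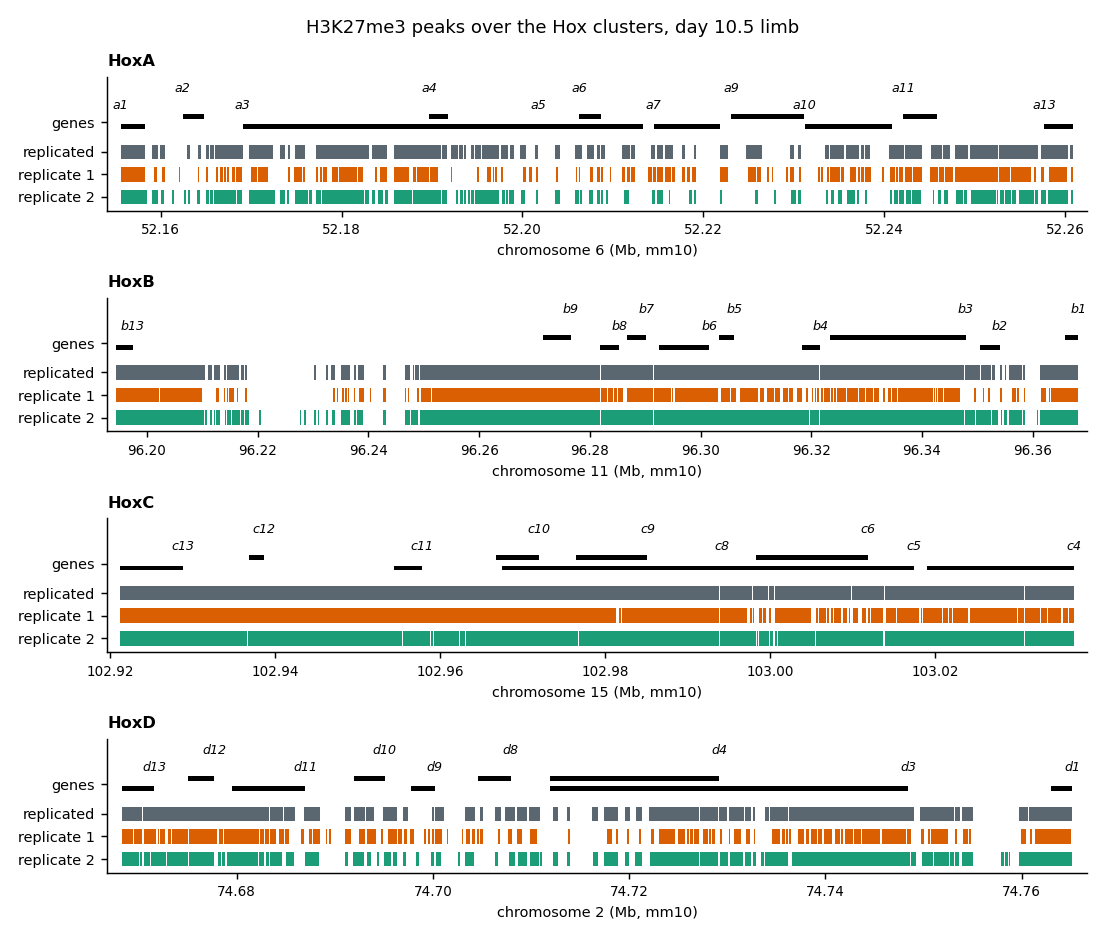
Map of H3K27me3 peaks over the 4 Hox clusters (x axis, position in Mb on mm10), with gene bodies as black bars labelled at their 3' ends and peak-covered stretches as coloured blocks for the replicated list, replicate 1 and replicate 2. HoxC is covered almost without a gap (99.3%), while HoxA (62.2%) and HoxD (71.2%) are broken up by gaps.

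The 10 strongest peaks are listed by gene, without a test of any theme among them. The highest fold enrichment, 28.2, belonged to a peak of 10736 bp over Adra2c, an adrenergic receptor gene (chromosome 5, 35274239 to 35284974, 32.1% of it exonic), with folds of 20.4 in replicate 1 and 28.3 in replicate 2. Next came a peak of 25.6 in the body of Sptbn4, an axonal spectrin gene (chromosome 7, 27400062 to 27411117). The promoter of Ptf1a followed at 23.8 (chromosome 2, 19440508 to 19458708), then those of Nrxn2 at 23.1 and of Neurog3 and Fam241b, which share a peak, at 23.0. A further peak, at 22.6, overlapped no annotated gene (chromosome 5, 147218604 to 147227649) and lay 29.9 kb from the TSS of Gsx1 and 42.3 kb from that of Pdx1. Rbfox3, a marker of mature neurons, Wnt10b, Wnt3a and Kcnc1 completed the 10 strongest, at folds of 22.3, 22.3, 21.8 and 21.4. Folds are the peak caller's own values; they rank peaks within a list and, between lists or chromosomes, serve as description only.

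The widest domains were on the X chromosome and around Irx3 and HoxC. Joining replicated peaks across gaps of up to 3 kb gave 21040 domains, of which 2689 spanned 10 kb or more, and 8 of the 10 with the longest covered length were X-linked. The first (X, 11327864 to 12015802) had 612 kb covered (458 kb in replicate 1 and 574 kb in replicate 2), and held no protein-coding TSS. It overlapped the histone gene H2al1j, whose TSS lies 0.042 kb outside its left edge, and on the right the nearest TSS, that of Bcor, was 64.8 kb away. The second (X, 99112776 to 99678385) had 548 kb covered and held the promoters of Efnb1, an ephrin gene, and Pja1. These 2 changed rank with the setting: the domain at Efnb1 came first in replicate 1 (492 kb), in replicate 2 (650 kb) and at a joining gap of 1 kb (548 kb). The third (X, 140329977 to 140892765) had 477 kb covered and held Frmpd3, Prps1, Tsc22d3, Mid2 and Tex13b. On the autosomes the first was a domain over Irx3 (chromosome 8, 91744791 to 92107130), with 306 kb covered (218 and 307 kb in the replicates), and a further 206 kb were covered in the adjoining domain (chromosome 8, 91507311 to 91737662), which overlaps Fto and lies between its TSS and that of Irx3. Between them in rank lay the HoxC domain, with 238 kb covered over 9 Hox genes and Smug1. The other X-linked domains held the promoters of Frmpd4, of Nhsl2, Rtl5, Pin4 and Ercc6l, of Hsd17b10, Ribc1, Smc1a and Iqsec2, and of Sh3kbp1 and Map3k15, or lay within Nhs.

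The X chromosome had a higher covered share than any autosome. Replicated peaks covered 13.3% of the X, against a median of 2.45% over the 19 autosomes and a range from 1.34% on chromosome 3 to 4.63% on chromosome 11. The X was above every autosome in each replicate: 8.08% against at most 3.50% in replicate 1, and 13.3% against at most 4.86% in replicate 2. Its ratio to the autosomal median was 4.16 and 5.19 in the replicates (4.68 ± 0.726, SD, n = 2) and 5.41 in the replicated list. The X held 26.3% of all replicated peaks on 6.49% of the genome, with a higher median fold (3.47 against 3.13) and width (687 against 581 bp) than autosomal peaks but a lower maximum fold (14.3 against 28.2). Promoters of 487 of 948 X-linked genes were marked (51.4%), against 26.2% of autosomal genes. At the most 5' TSS alone, 77.1% of 157 X-linked promoters with a CpG ratio of 0.6 or more were marked, against 26.0% of 7340 autosomal ones.

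**Figure D3:**
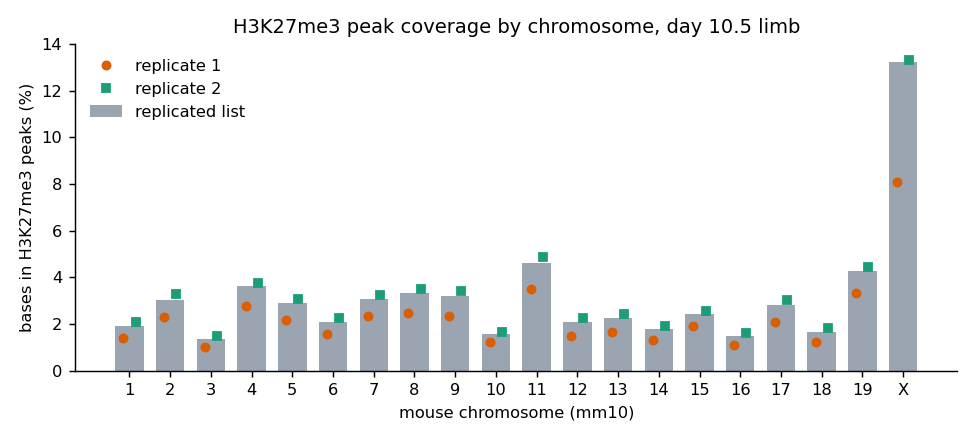
Share of each mouse chromosome (x axis) covered by H3K27me3 peaks (y axis, %); bars give the replicated list, circles replicate 1 and squares replicate 2. The X stands at 13.3%, 8.08% and 13.3%, and no autosome exceeds 4.86% in any of the 3 lists.

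Along the X the mark fell into blocks that left most of the chromosome bare. In 1 Mb bins, a division made after the covered share of the X was known, 96 of 167 X bins (57.5%) had under 1% of their bases covered, and the median X bin (0.533%) was below the median autosomal bin (0.924%). Against that, 48 bins in 10 separate runs exceeded the 95th percentile of autosomal bins (12%), and they held 94.3% of the bases covered on the X. The longest runs reached from 133 to 146 Mb (39% covered, 115 protein-coding genes), from 98 to 107 Mb (49.6%, 84 genes) and from 157 to 165 Mb (52.3%, 46 genes). The contrast with autosomes differed by gene number in the medians, though not bin by bin, since 12 of the 48 high bins held fewer than 5 genes and 36 of the 73 bins with 5 or more were high. X bins with 10 or more protein-coding genes had a median of 19.0% covered against 2.70% in such autosomal bins, and bins with 5 to 9 genes 8.68% against 1.16%, whereas bins with 1 to 4 genes had 0.0884% against 0.491%. Replicate 1 gave 9.67% and replicate 2 20.7% for the X bins richest in genes, and 2.13% and 2.87% for the autosomal ones.

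**Figure D4:**
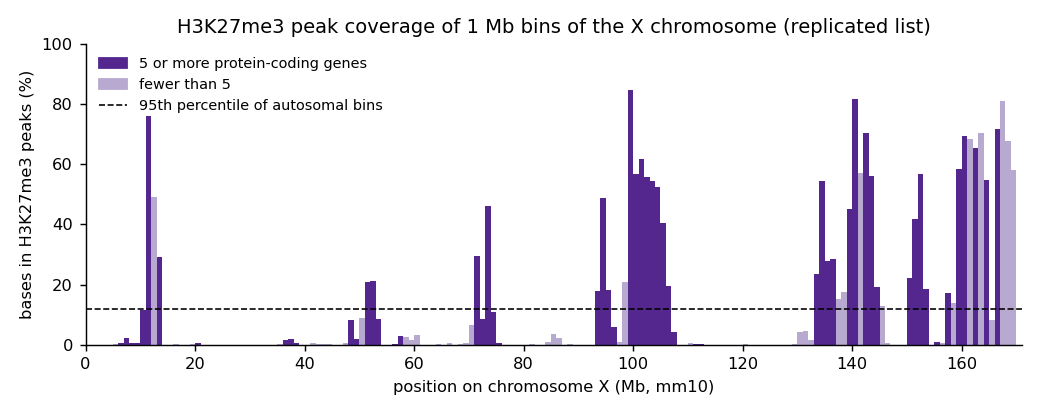
Share of bases in replicated H3K27me3 peaks (y axis, %) for 1 Mb bins along the X chromosome (x axis, Mb on mm10), dark where a bin holds 5 or more protein-coding genes; the dashed line is the 95th percentile of autosomal bins (12%). The mark is gathered in 10 runs of bins above that line, and 96 of 167 bins stay under 1%.

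The replicates marked largely the same genes and the same strong peaks, and differed among weak peaks. Promoter calls were the same for 93.6% of protein-coding genes: 5598 were marked in both lists, 533 only in replicate 1 and 854 only in replicate 2. Of the peaks of replicate 1, 64.9% were found in replicate 2 at an overlap of at least 50% of the shorter peak (58.5 ± 2.05% over the 19 autosomes, 83.7% on the X), and 41.4% of those of replicate 2 were found in replicate 1. In the strongest 10% by fold the shares were 99.2% and 97.2%, and in the weakest 10% 44.1% and 20.4%. A wider peak meets this overlap rule more easily, and the classes by fold were not matched on width. When the peaks of replicate 1 were shuffled within chromosomes 100 times, 6.47% on average and 6.67% at most overlapped (one-sided permutation p = 0.0099, the smallest that 100 shuffles allow). The shuffle placed each peak singly and evenly over its chromosome, assembly gaps included, and did not keep the clustering of peaks. Its p-value therefore only sets the overlap apart from scattered placement. The lists shared 49.6 Mb, which is 80.6% of the length covered in replicate 1, 54.8% of that in replicate 2 and a Jaccard index of 0.484. With 50% of both peaks required, 21.9% and 20.4% of the peaks were shared. Across the 27101 pairs formed in that way, which are not independent replicates, the folds of the 2 lists had a Spearman correlation of 0.643.

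**Figure D5:**
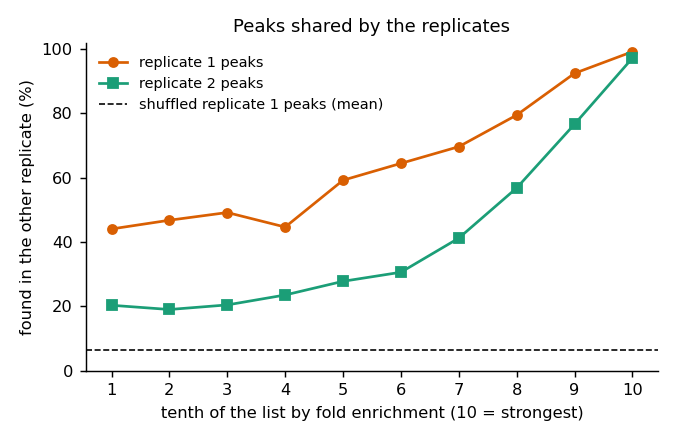
Share of each replicate's peaks found in the other replicate (y axis, %) by fold enrichment in its own list. Folds are parted into 10 equal classes (x axis, 10 strongest). The dashed line is the mean of 100 shuffles of all replicate 1 peaks (6.47%). No shuffle was run for replicate 2 or by class. Sharing goes from 44.1% to 99.2% for replicate 1 and from 20.4% to 97.2% for replicate 2.

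Few promoters were well covered in a single replicate. At least 50% of the window was covered in replicate 2 and none in replicate 1 for 14 genes, led by Otof, Srpx2, Uts2r, Polrmt and Ppp1r14a, and the reverse held for 1 gene, Rab27a. Actb, which encodes cytoplasmic beta-actin, was among the 14, with 93.1% of its promoter window covered in replicate 2 and 0 in replicate 1. Its peak (chromosome 5, 142904635 to 142906682, within the gene) had a fold of 7.03, the highest of the 69767 replicate 2 peaks without any overlap in replicate 1, and stood at 4.70 in the pooled and replicated lists.

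The replicated list proved to be a subset of the pooled list. All 71422 of its peaks recurred in the pooled list with the same position, fold and p-value, and they made up 42.3% of the pooled peaks and 78.0% of their length. By overlap of at least 50% of the shorter peak, 52675 of them (73.8%) were found in both replicates' own lists, 14326 only in that of replicate 2, 3505 only in that of replicate 1 and 916 in neither. Every pooled peak found in both was kept, so the remaining 18747 were admitted by a criterion that the files do not show. The Actb peak is 1 example, present in replicate 2 and in the pooled data and counted as marked in the replicated list.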

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

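No test in this part was chosen after its result was seen. A signal appeared outside the chromosomes analysed: the pooled list held 1 peak on an unlocalised scaffold of chromosome 4 (525 to 689 on that scaffold, 165 bp), with a fold enrichment of 2.35 and a −log10 p of 4.07. It was in neither replicate's own list nor in the replicated list, and no explanation for it was tested.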

How the results depend on the processing

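Restriction to autosomes was chosen after the X chromosome was seen to stand apart. Of 264 alternatives for the 24 gene lists 249 left the call as it was, and 18 lists kept theirs throughout. For the 18 other results, 27 of 62 alternatives left the value within a set margin and 35 moved it. The margin differed by result. For a mean of the 2 replicates it was their SD, which leaving 1 replicate out never exceeds. Covered length thus counted as unmoved at 61.5 and 90.5 Mb around a mean of 76.0 Mb. For shares of peaks it was 50% of the width of the narrow Wilson interval, which small changes exceed. These counts therefore do not measure robustness. The cause of the changes was not tested. Differences below are percentage points over other genes. Cartilage and bone genes lost the call with 1 gene per 100 kb (27.7). Blood markers lost it at the most 5' TSS (21.5), in the pooled list (27.1), with 1 gene per 100 kb (34.4), on autosomes (27.7) and without replicate 2 (25.1 to 30.2 with each replicate left out). Endothelial markers gained a call at 500 bp (29.9), at the most 5' TSS (28.7) and with 50% of the window covered (27.6). Housekeeping genes became lower on autosomes (−22.4), against CpG-matched lists (−23.0) and without replicate 2 (−24.8 to −15.5), and imprinted genes higher with 50% of the window covered (21.5) and on autosomes (17.2). Polycomb group genes changed direction with 50% of the window covered (−1.30), with no call in either case. A −log10 q of at least 2 left a mean of 99676.5 peaks per replicate. The share of replicate 1 peaks found in replicate 2 became 72.1% at 1 bp, 21.9% with 50% of both peaks, 69.1% at that q and 63.7% in lists of equal length, and that of replicate 2 peaks 47.6%, 20.4%, 40.6% and 43.2%. Replicated peaks found in both replicates were 74.4% at 1 bp and 57.0% at that q. Marked promoters were 23.9% at 500 bp, 31.1% at 2500 bp, 25.2% at the most 5' TSS, 32.9% in the pooled list, 18.5% with 50% of the window covered and 26.2% on autosomes. With a 2500 bp window the exon, intron and intergenic ratios were 1.47, 0.875 and 0.697. The CpG difference was 0.0631 at 500 bp. The widest domain had 733 kb covered at a gap of 5 kb, and HoxA was 67.2% covered in the pooled list. With each replicate left out in turn the ranges were 123895 to 133099 peaks, 4.16 to 5.19 for the X ratio, 28.3% to 29.8% of promoters, 4.29 to 5.37 (promoter), 1.75 to 1.94 (exon), 0.982 to 1.01 (intron) and 0.726 to 0.770 (intergenic) for position, 492 to 650 kb for the widest domain (then the one at Efnb1, as also at a gap of 1 kb), 47.3% to 52.6% for HoxA, 66.3% to 82.0% for HoxB, 93.4% to 97.9% for HoxC and 54.2% to 67.1% for HoxD. With 1 group of 2 replicates these ranges show each replicate alone and no paired analysis was possible because there was no second group.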

Other observations

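In the part that follows, the test without the most covered X bins, the test against matched autosomal bins, the test without Kdm6a and the limb against neural permutation test, with its version at the most 5' TSS, were chosen after the results were seen. The other tests of explanations were set after the patterns they concern were seen but before their own values were. Among X-linked genes known to escape X inactivation, the promoters of Ddx3x, Eif2s3x, Kdm6a and Pbdc1 carried no peak, while those of Utp14a, Kdm5c and Mid1 were covered over 35.1%, 33.4% and 92.9%.

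The X chromosome had a covered share 5.41 times the autosomal median. Gene density and base composition did not account for it: the X lay 31.4 residual SDs above the line fitted over the 19 autosomes, an extrapolation to a negative cover (−0.104%) since its GC content (39.3%) was below that of any autosome (40.5% or more), but X bins also had 16.6 times the cover of autosomal bins of like gene number and GC content (13.9 and 15.4 in the replicates). A few regions of the X, such as multicopy families, were left undecided, as the tests of this disagreed. The median X bin had 0.577 times the cover of the median autosomal bin, as that explanation predicted. Without the most covered 10% of bins on both sides, the X was still 7.98% covered against 1.42% on the autosomes. That is a ratio of 5.62 (4.18 and 5.24 in the replicates). The excess was thus not confined to those X bins, though 48 bins in 10 runs held 94.3% of the bases covered on the X. The mark of the inactive X in female cells was also left open. Of the escape genes, taken whatever their CpG ratio, 3 of 7 were marked. Of X-linked genes outside that list with a ratio of 0.6 or more, 121 of 151 were marked (Fisher's exact p = 0.0391). But without Kdm6a, whose state had been seen before the test, Fisher's exact p was 0.108 with 6 genes. The sets were also not matched on CpG content. The sexes were mixed within each pool, so no difference between them was tested.

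Replicate 1 covered 61.5 Mb and replicate 2 covered 90.5 Mb. Fewer reads behind replicate 1 are consistent with a median −log10 p ratio of 0.784 at 27101 shared peaks, beside a fold ratio of 1.03, though no read count was at hand to check it. Weaker enrichment in replicate 1 was left undecided by the fold ratio at the strongest 10% of those peaks, 0.918, where the −log10 p ratio was 0.617. Only peaks called in both lists entered these ratios. The fold ratio of 1.03 therefore cannot by itself part fewer reads from weaker enrichment. The pools also differed in embryos (69 and 51), which was not tested.

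Limb transcription factors had less of their promoter windows covered than neural ones, 56.8% (SD 40.8, 31 genes) against 98.4% (SD 8.11, 35 genes). Permuted list labels gave no difference as large as 41.6 points (permutation p = 1e-05, the smallest that 100000 draws allow; 0.00276 after multiplication by the 276 pairs of lists, as this pair was picked by its values), and the difference was larger in each replicate (53.3 and 44.3). CpG and GC content of the promoters did not account for it, as 101.8% of the difference was left after their fit. At the most 5' TSS, where that content was computed, the difference was 42.4 points and 101.6% was left. No biological explanation was tested.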
